A study of Arabidopsis thaliana with 24 samples.

How the data were processed

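The series measured transcripts in Arabidopsis thaliana seedlings by hybridising total RNA to oligonucleotide arrays. The plants were wild-type Columbia (Col), the nph4-1 mutant of ARF7, the arf19-1 mutant of ARF19 and the nph4-1 arf19-1 double mutant, grown for 7 days in liquid culture with 1.5% sucrose under 16 h light and 8 h dark. Each genotype received 5 µM indole-3-acetic acid (IAA, the natural auxin) or the ethanol solvent for 2 h at 24 °C. Per the labels, each of the 8 groups has 3 arrays, numbered 1 to 3, which gives 24 arrays.

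The deposited values are log2 signal, 1 value per probe set and array, made by the authors with a floor of 50 in linear units, which is 5.64 in log2. The method by which the authors summarised and scaled the arrays was not stated in the sources used here. At least 35.6% and at most 36.7% of the values of an array lay at the floor, the array medians ran from 6.645 to 6.758, and the ratio of the highest to the lowest median was 1.08 in linear units, so no shift between arrays was made. No pair of arrays shared over 0.02% of its values above the floor. The labels state that the tables of Col control 2 and 3 were replaced after an earlier release. The number of arrays limits the precision.

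Of 22810 probe sets, 64 control probe sets were left out, and 6989 of the other 22746 lay at the floor on all 24 arrays and were left out of the tests. The design fixed before the data were examined tested all probe sets but the controls, so this is a departure from it, and an alternative adjusted over all of them. The 15757 probe sets left were tested. Names came from the annotation supplied for the platform, which pairs 13513 probe sets with 1 gene, 503 with several and does not list 8794. Of the 13513, 13436 were found in the RefSeq gene table (assembly TAIR10.1), which was used for names only. Of the tested probe sets 8616 had 1 gene, and only these are named. No probe set was paired with ARF7 or ARF19, so the levels of both genes, which the design had included, were not analysed here.

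A model with the 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with 16 residual degrees of freedom. The contrasts were the IAA response of each genotype, each mutant against Col without IAA, each mutant's IAA response minus that of Col, and the non-additivity, which is the double mutant's response minus those of both single mutants plus that of Col. All tests are two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast at a threshold of 0.05. The errors of log2 changes are standard errors from this fit. A probe set at the floor in several groups shows no spread there, which lowers the pooled error of that fit. The difference contrasts share the Col arrays, and the contrasts without IAA share the Col control arrays. The labels do not say whether the 3 arrays of a group are separate cultures, so the p-values may cover technical spread only.

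The rule for named genes took called probe sets with 1 gene. For the IAA response in Col it took the 12 largest rises and the 12 largest falls among those whose 3 treated arrays all lay on one side of the 3 control arrays, which chance gives to 10% of probe sets. For the difference of the double mutant it took the 10 largest in each direction and for every other comparison the 5 largest in each direction. From each gene list described it took up to 4 called members, or the 2 with the largest change where none was called. Where all arrays of a group are at the floor the fold is a lower bound. Of 29 gene lists fixed before the data were examined, 3 had at least 5 tested members. After the annotation had been read, 20 further lists were made from it, of which 19 had at least 5. The 22 lists were tested with camera of limma at the preset correlation of 0.01, with Benjamini-Hochberg over the lists of a contrast, and again with an estimated correlation and with fry.

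The model was tested on simulated data of 15757 probe sets. The simulated noise was independent between probe sets and between arrays, with the same spread in all groups. The real arrays had weights from 0.14 to 7.9 and deviations that correlated between arrays, so the rates below may not hold for them. For the IAA response in Col it recovered 67 of 100 changes of 1.5-fold and 91 of 100 of 2-fold, with 5.2% false calls. For the difference of the double mutant it recovered 36 and 82 of 100, with 5.7% false calls, and for the non-additivity 13 and 53 of 100, with 3.8%.

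The alternatives fixed beforehand were quantile normalization, each array at the same median, a filter on dim probe sets, plain eBayes, a fit of only the arrays compared, a block for the replicate number, array quality weights, leaving out each array in turn, an adjusted p under 0.01, a minimum change of 2-fold, and a selection of probe sets on the mean response of the 4 genotypes. A pseudocount of 1 or 64 was not run, since the values were already logarithms. Chosen after seeing the data were the adjustment over all probe sets, a fit without both outlying arrays, probe sets above the floor on at least 12 arrays, and the contrast of the responses of nph4-1 and arf19-1. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.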

Results

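Transcript signals of 22810 probe sets were compared in seedlings of 4 Arabidopsis genotypes, each with and without IAA. Col is the wild type, nph4-1 carries a mutation in ARF7 and arf19-1 a mutation in ARF19, both of which encode transcription factors that activate genes in response to auxin. Each of the 8 groups had 3 arrays, so every value below rests on 3 arrays per group. As the depth of an array, the median log2 signal lay between 6.645 and 6.758 and the highest signal was at least 13.23. Between 35.6% and 36.7% of the values of an array lay at the floor. Col control 3 and nph4-1 IAA 1 stood apart from their replicates, with array weights of 0.19 and 0.14 estimated by limma.

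The first comparison asked which genes IAA changed within 2 h in wild-type seedlings. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, had the largest rise among the genes with a name, 49.6-fold (log2 5.63, SE 0.18, n = 3 per group), from a log2 signal of 7.38 (SD 0.44) to 13.01 (SD 0.19), the latter close to the highest signals of the arrays. WES1, also known as GH3.5, rose 18.1-fold (SE 0.37 in log2), and GH3.1, at the floor on every Col control array, rose at least 7.04-fold (SE 0.17). The auxin response repressor IAA29 rose at least 18.9-fold (SE 0.14) and LBD29, a transcription factor of lateral root initiation, at least 11.8-fold (SE 0.11), both from the floor. HAT2, a homeodomain-leucine zipper transcription factor, rose 7.75-fold (SE 0.11). The other named genes with the largest rises were AT4G17350 at 8.02-fold, AT1G62770 at 7.88-fold, AT3G26760 at 7.58-fold, AT2G39980 at 6.68-fold, AT5G40590 at 6.54-fold and, from the floor, AT1G64405 at 6.31-fold or more.

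Among the falls with IAA in Col, AT4G25250 went from above the floor to the floor on all 3 arrays, a log2 change of -2.29 (SE 0.12) and a fall of at least 4.89-fold. The log2 changes were -2.08 for AT1G72200 (SE 0.18), -2.02 for AT3G45700 (SE 0.19), -1.95 for AT3G01260 (SE 0.18) and -1.88 for the secreted class III peroxidase AT3G01190 (SE 0.12). AT5G60520 fell to the floor, a log2 change of -1.72 or below (SE 0.13), and AT4G11210 (-1.72, SE 0.15), AT3G13760 (-1.51, SE 0.11) and AT3G32030 (-1.43, SE 0.16) also fell. The AP2/ERF transcription factor gene tny fell 2.65-fold (SE 0.15 in log2), AT2G28780 changed by -1.39 (SE 0.21) and AT4G11190 by -1.38 (SE 0.22). The adjusted p of these 24 genes ran from 1.5e-15 for GH3.3 to 0.00011 for AT4G11190. All 24 calls held in every alternative that tested the gene.

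In total 2026 probe sets changed with IAA in Col, 998 higher and 1028 lower, and 405 of them changed at least 2-fold, 293 higher and 112 lower. Only 19 of the 50 largest called changes had a gene name. When only the Col arrays were fitted, 893 probe sets passed.

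**Figure D1:**
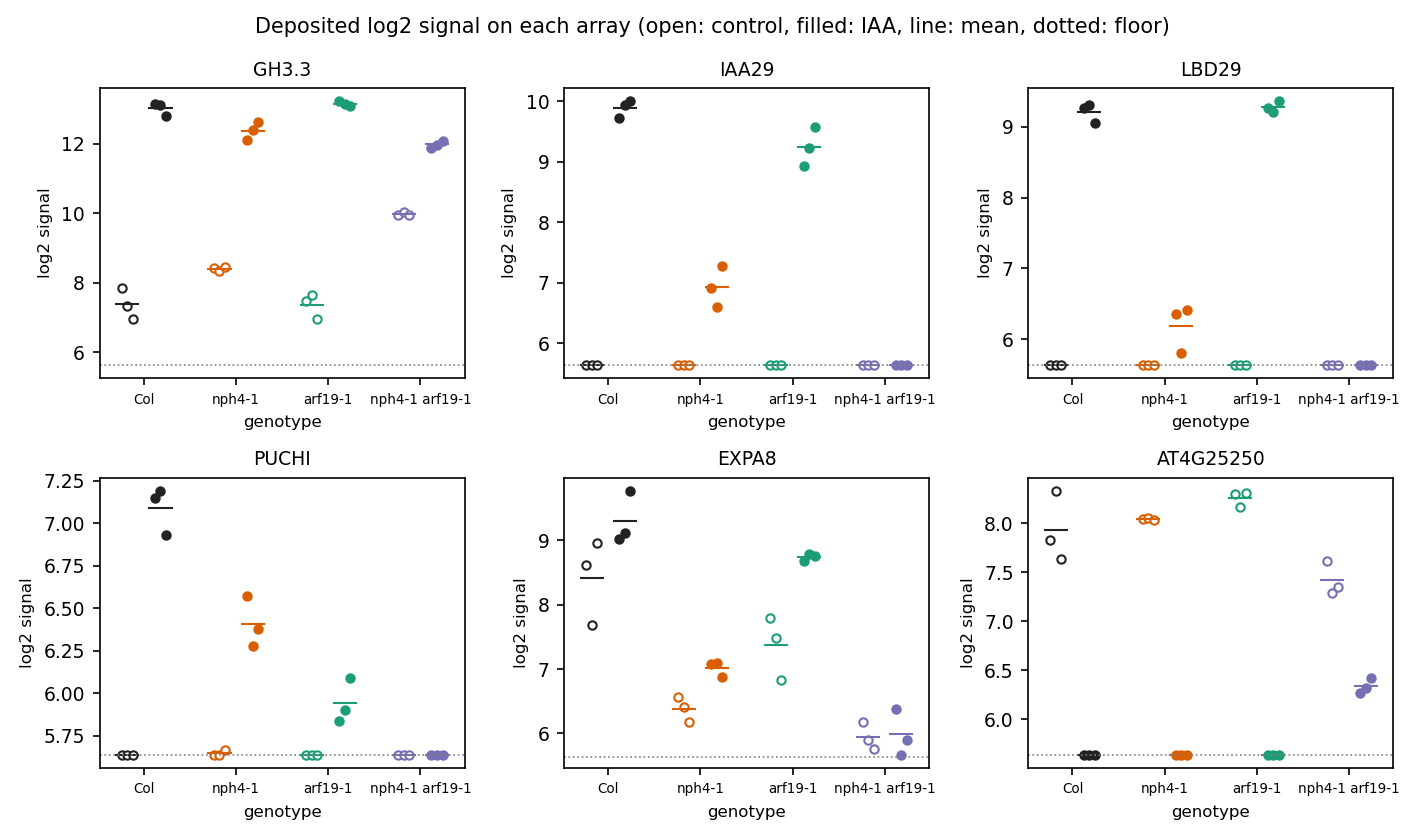
Log2 signal of 6 genes on each of the 24 arrays by genotype, with open points for ethanol controls, filled points for IAA, a line at the mean of 3 arrays and a dotted line at the floor. GH3.3 rose from 7.38 to 13.01 in Col and from 9.97 to 11.98 in nph4-1 arf19-1, while IAA29 and LBD29 lay at the floor on all 6 arrays of the double mutant.

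By gene list in Col, 3 of 5 tested Aux/IAA repressors rose, namely IAA29, IAA30 (log2 1.60, SE 0.15) and IAA18 (0.48, SE 0.13), and 3 when adjusted over the list alone. Only these 5 of the 29 Aux/IAA genes listed had a named, tested probe set, so most of the family was not covered. Of the 4 GH3 genes, 3 rose, and GH3.17 had a log2 value of 0.11 (SE 0.21). Both tested LBD genes rose, LBD16 by 1.95 (SE 0.13), as did the root primordium factor PUCHI by 1.45 (SE 0.08), WAG2, a kinase that directs auxin carriers, by 1.33 (SE 0.20), and RTE1 of the ethylene response by 1.1 (SE 0.09). YUC6, an auxin synthesis enzyme, fell by 0.66 (SE 0.17). Among cytokinin genes RR16, also known as ARR16, rose by 0.31 (SE 0.07) and ARR15 had a value of 0.00 (SE 0.04). The stress-induced WRKY53 rose by 0.98 (SE 0.22) and STZ, also known as ZAT10, by 1.09 (SE 0.32), and GSTU26 of the glutathione transferases fell by 1.33 (SE 0.18) while GSTU25 did not pass at 0.56 (SE 0.27). No tested gene of heat shock (2), hypoxia (4), nuclear photosynthesis proteins (3), root hairs (2) or the stomatal lineage (2) passed in limma, nor when adjusted over the list alone. The clock gene GI (log2 -0.42, SE 0.17) did not pass in limma either. As the only tested clock gene it had just an unadjusted limma p under 0.05, which 3710 probe sets had in this contrast. The lists of SAUR, ARF, ethylene synthesis, gibberellin, brassinosteroid, cell cycle, jasmonate, endodermis, xylem, and ABA and cold genes had no tested named member and were not analysed here.

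Cell wall genes moved in both directions with IAA in Col. Of 9 XTH genes, which remodel xyloglucan, XTH19 rose by 1.34 (SE 0.19), XTH18 by 1.24 (SE 0.14) and XTH33 by 0.86 (SE 0.10), and XTH16 fell by 0.75 (SE 0.19), with 5 called in limma and 5 when adjusted over the list alone. Of 13 expansins, EXPA4 rose by 1.51 (SE 0.20), EXPA20 by 0.96 (SE 0.12) and EXPA8 by 0.89 (SE 0.27), EXPB1 fell by 0.77 (SE 0.12), and 4 passed adjusted over the list alone. Of 8 GH9 glucanases 2 rose, GH9B13 by 1.31 (SE 0.14) and GH9C2 by 0.56 (SE 0.15). Of 40 class III peroxidases 9 rose and 5 fell, with AT5G39580 at 2.04 (SE 0.15), AT5G14130 at 1.58 (SE 0.18) and AT4G30170 at -1.3 (SE 0.13) beside AT3G01190. Of 9 beta-glucosidases 3 fell, BGLU40 by 0.65 (SE 0.13), BGLU15 by 0.54 (SE 0.11) and BGLU16 by 0.39 (SE 0.08).

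Tested against all other probe sets with camera at its preset correlation, the Aux/IAA list was higher in Col with IAA (adjusted p = 2e-04, adjusted p = 0.067 with an estimated correlation). The TBL genes, which acetylate wall polymers, were lower (5 of 16 fell, TBL25 by 0.94, SE 0.10, adjusted p = 0.018, adjusted p = 0.12 with an estimated correlation). SWEET sugar transporters were lower (3 of 7 fell, SWEET2 by 0.85, SE 0.13, adjusted p = 0.023, adjusted p = 0.57 with an estimated correlation). WRKY factors were higher (1 of 5 rose, WRKY53, adjusted p = 0.037, adjusted p = 0.12 with an estimated correlation). Cytosolic ribosomal proteins were higher (2 of 103 rose, AT5G59240 by 0.63, SE 0.11, and AT5G39850 by 0.42, SE 0.12, adjusted p = 0.037, adjusted p = 0.65 with an estimated correlation). The median log2 change of this list was only 0.041. In a fit of the Col arrays alone the calls of IAA18, XTH16, EXPA8, YUC6, STZ, RR16, GH9C2, BGLU16, BGLU40 and AT5G39850 ended, as did that of BGLU15 with array quality weights. Leaving out 1 array, with each of the 6 Col arrays ending at least 1 call, also ended those of IAA18, XTH16, EXPA8, YUC6, STZ, GH9C2 and AT5G39850, with an adjusted p of at most 0.19 over these omissions.

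The second comparison asked how much of this response needs ARF7. In nph4-1 GH3.3 still rose 15.6-fold (log2 3.97, SE 0.18) and WES1 5.65-fold (SE 0.37), and AT5G40590 (4.59-fold), the peroxidase AT5G39580 (3.88-fold) and AT4G27280 (3.57-fold) followed. AT4G25250 fell to the floor, at least 5.27-fold, and so did AT5G04120, at least 2.54-fold. AT3G45700 (log2 -1.72, SE 0.19), AT4G11210 (-1.61, SE 0.15) and the peroxidase AT2G18980 (-1.61, SE 0.10) also fell. In total 397 probe sets changed in nph4-1, 271 higher and 126 lower, and 101 at least 2-fold. Of the 271, 225 were also higher in Col, where independent sets would share 17.2, and of the 126, 95 were also lower, against 8.22. The count was 258 without nph4-1 control 3, and 153 in a fit of the nph4-1 arrays alone, in which WES1 did not pass. With array quality weights it was 838, and with the replicate number as a block 444.

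The response of nph4-1 was smaller than that of Col for LBD29 (log2 difference -3.02, SE 0.16) and for IAA29 (-2.96, SE 0.20). Because both genes, and GH3.1, lay at the floor without IAA, these differences compare signals under IAA. AT3G50340 rose by 2.17 in Col and had -0.27 in nph4-1, a difference of -2.44 (SE 0.29). GH3.1 (-2.32, SE 0.24), AT2G39980 (-2.30, SE 0.28), HAT2 (-1.84, SE 0.16) and GH3.3 (-1.66, SE 0.25) also responded less, whereas the smaller rise of WES1 did not pass (adjusted p = 0.1). Part of the smaller rise of GH3.3 lies in its level without IAA, 8.33 to 8.46 on the nph4-1 arrays and 6.97 to 7.84 on those of Col. For GH3.3, the rise of Col added to the level of nph4-1 without IAA would pass the highest signal of the arrays, and for 19 of the 446 probe sets counted below, among them AT1G72200 and SWEET2, the fall of Col would end below the floor, so these differences are partly set by the limits of the signal. Falls were also smaller, by 1.78 (SE 0.26) for AT1G72200, 1.56 (SE 0.26) for AT3G01260 and 1.28 (SE 0.29) for AT2G28780. The log2 response was higher by 1.52 (SE 0.28) for AT5G62360 and by 1.37 (SE 0.22) for AT5G07580. In all, 446 probe sets differed in response, 183 with a higher and 263 with a lower log2 response in nph4-1, and 214 in a fit of the arrays compared. AT2G28780 did not pass in that fit or without Col control 3, Col IAA 1 or nph4-1 control 1, with adjusted p up to 0.058 over the omissions.

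By list in nph4-1, IAA29 (1.28, SE 0.14) and IAA30 (0.94, SE 0.15) rose among 5 Aux/IAA genes, and the list was higher (adjusted p = 0.0048, adjusted p = 0.3 with an estimated correlation). Its response was smaller than in Col (adjusted p = 0.0021, adjusted p = 0.16 with an estimated correlation), with IAA29 as the member called. Cytosolic ribosomal proteins were higher in nph4-1 as a list with none of 103 called (adjusted p = 1.9e-07, adjusted p = 0.42 with an estimated correlation). The median log2 change of the list was 0.098, the largest values being 0.40 (SE 0.11) for AT5G59240 and 0.29 (SE 0.15) for AT3G55170. The lists of glutathione transferases (GSTU27, 0.80, SE 0.15, adjusted p = 0.021), CYP71B enzymes (none called, CYP71B28 0.70, SE 0.22, adjusted p = 0.021), SWEET transporters (SWEET2 0.70, SE 0.18, adjusted p = 0.041) and tetraspanins (TET8 0.48, SE 0.11, adjusted p = 0.0032) had a higher log2 response in nph4-1 than in Col. With an estimated correlation these adjusted p-values were 0.29, 0.29, 0.49 and 0.29. A fit of the arrays compared ended the calls of IAA30, GSTU27, SWEET2 and TET8, and the omission of 1 array ended those of SWEET2 (13 of 24, adjusted p up to 0.11) and TET8 (4 of 24, up to 0.064).

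The third comparison asked the same of ARF19. In arf19-1 GH3.3 rose 55-fold (log2 5.78, SE 0.18), WES1 by 4.12 in log2 (SE 0.37), LBD29 at least 12.4-fold (SE 0.11), IAA29 at least 12.1-fold (SE 0.14) and AT5G62280 8.57-fold (SE 0.25), the last with a log2 response of 2.43 in Col. With IAA the GH3.3 signal lay close to the highest signals of the arrays in arf19-1 as in Col, which limits how far these rises can differ. AT4G25250 fell to the floor, at least 6.12-fold, and AT1G72200 (log2 -2.00, SE 0.18), AT3G45700 (-1.83, SE 0.19), AT3G01190 (-1.80, SE 0.12) and AT4G11210 (-1.62, SE 0.15) also fell. In total 1592 probe sets changed, 770 higher and 822 lower, and 342 at least 2-fold. Of these, 617 were also higher and 583 also lower in Col, against 48.8 and 53.6 for independent sets. Of 5 Aux/IAA genes 3 rose, IAA29, IAA30 by 1.3 (SE 0.15) and IAA18 by 0.47 (SE 0.13), the last not without arf19-1 control 1 or arf19-1 IAA 1 or 3, with adjusted p up to 0.1. The list was higher (adjusted p = 0.00023, adjusted p = 0.07 with an estimated correlation), and 5 of 16 TBL genes fell (TBL38 by 0.83, SE 0.17, adjusted p = 0.033, adjusted p = 0.23 with an estimated correlation). With array quality weights, which put 7.9 on arf19-1 control 2, the count was 5231.

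The response of arf19-1 differed from that of Col for 41 probe sets, 9 with a higher and 32 with a lower log2 response. PUCHI rose by 1.45 in Col and had 0.30 in arf19-1, a difference of -1.15 (SE 0.11). AT2G23060, at the floor without IAA, rose by 1.41 in Col and had 0.00 in nph4-1 and 0.03 in arf19-1, a difference of -1.39 (SE 0.07) for arf19-1. AT3G09280 (-1.39, SE 0.19), AT3G51410 (-1.34, SE 0.13), AT2G41380 (-1.28, SE 0.27) and AT4G17350 (-1.26, SE 0.17) also responded less in arf19-1. PUCHI, AT3G09280 and AT3G51410 also lay at the floor without IAA in Col and arf19-1, so that these differences compare signals under IAA. The log2 response was higher for the peroxidase AT2G39040 (1.11, SE 0.20), AT1G19900 (0.93, SE 0.18) and AT3G46720 (0.59, SE 0.11), and for AT4G37850, which left the floor on the arf19-1 IAA arrays alone. UGT glycosyltransferases had a lower log2 response than in Col as a list with none of 31 called (UGT72E1 -0.80, SE 0.35, UGT85A4 -0.59, SE 0.25, adjusted p = 0.013, adjusted p = 0.64 with an estimated correlation). The median log2 response of the list was 0.006 in Col and -0.186 in arf19-1. In a fit of the arrays compared 19 probe sets passed, and with the filter on dim probe sets 27. That fit ended the calls of AT2G39040, AT1G19900, AT3G46720 and AT4G37850, and AT4G37850 was lost in 23, AT2G41380 in 14 and AT1G19900 in 8 of the 24 omissions of 1 array.

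The next comparison asked what was left of the response with both genes mutated. In nph4-1 arf19-1 GH3.3 rose 4.01-fold (log2 2.00, SE 0.18), from 9.97 to 11.98, STZ 2.86-fold (SE 0.32), AR781 2.16-fold (SE 0.18), AT4G27280 2.12-fold (SE 0.22) and AT5G40590, from the floor, at least 2.1-fold (SE 0.24). HAT2 rose by 0.56 (SE 0.11) in log2. AT5G04120 (log2 -1.61, SE 0.22), AT4G25250 (-1.08, SE 0.12), AT1G70720 (-0.97, SE 0.18) and the peroxidase AT3G01190 (-0.76, SE 0.12) fell. IAA29, LBD29 and GH3.1 lay at the floor on all 6 arrays of the double mutant. In total 66 probe sets changed, 53 higher and 13 lower, and 18 at least 2-fold. Of the 53, 42 were also higher in Col, against 3.36 for independent sets, and 10 of the 13 were also lower, against 0.848. TBL genes were lower as a list with none of 16 called (TBL41 -0.33, SE 0.15, TBL34 -0.26, SE 0.14, adjusted p = 0.0052, adjusted p = 0.13 with an estimated correlation).

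Without double-mutant control 1, 2 or 3 the count of the double mutant was 43, 33 and 33, and without IAA array 1, 2 or 3 it was 38, 42 and 36. It was 218 with array quality weights and 70 with the replicate number as a block. The calls of STZ, AT4G27280, AT5G40590, AT1G70720 and HAT2 ended in 16, 7, 18, 4 and 6 of all 24 omissions of 1 array, with adjusted p up to 0.23, 0.21, 0.31, 0.098 and 0.18, while those of GH3.3, AR781, AT5G04120, AT4G25250 and AT3G01190 held in every alternative that tested the gene.

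Against Col, the response of the double mutant was smaller for IAA29 (log2 difference -4.24, SE 0.20), GH3.3 (-3.63, SE 0.25), LBD29 (-3.56, SE 0.16), WES1 (-3.11, SE 0.52), AT4G17350 (-3.05, SE 0.17) and GH3.1 (-2.82, SE 0.24). AT3G26760 (-2.68, SE 0.27), AT1G64405 (-2.68, SE 0.23), AT2G39980 (-2.49, SE 0.28) and AT1G62770 (-2.49, SE 0.16) followed. IAA29, LBD29 and GH3.1 lay at the floor on all Col control and double-mutant arrays, so that their values restate the signal of Col with IAA above the floor. GH3.3 differs from these. Without IAA its log2 signal was 9.94 to 10.03 on the double-mutant arrays and 6.97 to 7.84 on those of Col. With IAA it was 11.88 to 12.08 and 12.8 to 13.14. Most of its smaller response therefore lies in the higher level without IAA. Falls were smaller by 1.92 (SE 0.26) for AT1G72200, 1.69 (SE 0.26) for AT3G01260, 1.48 (SE 0.19) for AT5G60520 and 1.47 (SE 0.26) for AT3G45700. For AT5G62360, AT2G28780, AT4G20460, AT3G20015, AT3G13760 and AT3G32030 the log2 response was higher by 1.44 (SE 0.28), 1.4 (SE 0.29), 1.38 (SE 0.21), 1.38 (SE 0.24), 1.35 (SE 0.15) and 1.32 (SE 0.22). AT2G28780, AT3G13760 and AT3G32030 were among the largest falls of Col, so for them this is a fall that was smaller or absent in the double mutant. All 20 calls held in every alternative that tested the gene. For GH3.3, the rise of Col added to the level of the double mutant without IAA would pass the highest signal of the arrays, and for 39 of the 640 probe sets, among them AT1G72200, AT5G60520, AT3G45700 and AT3G32030, the fall of Col would end below the floor, so these differences are partly set by the limits of the signal. In all, 640 probe sets differed, 234 with a higher and 406 with a lower log2 response, and 307 by at least 2-fold.

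By list, the response of the double mutant was smaller for IAA29 and IAA30 of 5 Aux/IAA genes, for 3 of 4 GH3 genes, for both LBD genes (LBD16 -1.83, SE 0.19), for HAT2 (-2.39, SE 0.16), PUCHI (-1.45, SE 0.11, at the floor in the double mutant), RTE1 (-1.02, SE 0.13) and WAG2 (-1.09, SE 0.29), for XTH19 (-1.52, SE 0.28), XTH33 (-0.85, SE 0.15) and XTH18 (-0.81, SE 0.19), and for EXPA4 (-1.26, SE 0.29) and EXPA20 (-0.82, SE 0.17). The Aux/IAA list was lower against other probe sets (adjusted p = 2.2e-05), and it alone held with an estimated correlation (adjusted p = 0.031) among all list calls of the 11 contrasts. That list holds 5 of the 29 Aux/IAA genes listed. Leaving out single Col or double-mutant arrays ended the calls of WAG2 (8 omissions, adjusted p up to 0.1) and XTH18 (4 omissions, up to 0.06).

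**Figure D2:**
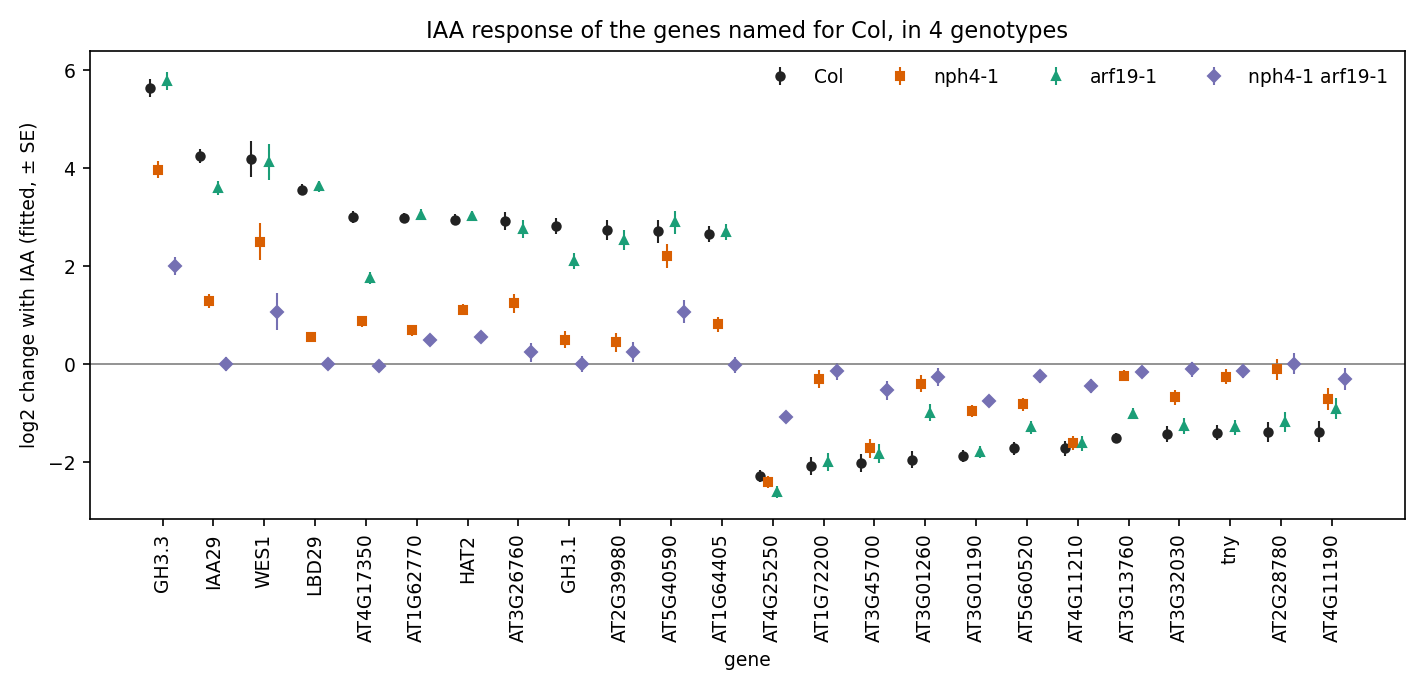
Log2 change with IAA (fitted, ± SE, 3 arrays per group) of the 24 genes named for Col, in the 4 genotypes. Points of arf19-1 lie near those of Col for GH3.3 (5.78 and 5.63), where the signal with IAA is close to the highest of the arrays in both. Those of nph4-1 arf19-1 lie at 2.00 for GH3.3 and 0.00 for IAA29.

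The share of the Col response kept in each mutant was taken over the 293 probe sets raised and the 112 lowered at least 2-fold in Col. The median rise was 1.44 in Col, 0.54 in nph4-1, 1.31 in arf19-1 and 0.14 in the double mutant, which is 37.8% (SD 5.65 over 3 arrays), 90.7% (SD 5) and 9.54% (SD 4.09) of that in Col. For the lowered probe sets the shares were 32.5% (SD 9.67), 92.9% (SD 4.64) and 16.4% (SD 5.04). Each SD is that of the 3 IAA arrays of a genotype, each set against the mean of its controls. It leaves out the spread of the control arrays and of the Col median. The floor also enters these shares, since a probe set at the floor on all arrays of a mutant counts as a response of 0. In the double mutant the lower quartile of the rises was 0, and IAA29, LBD29 and GH3.1 are such cases. Among probe sets above the floor on at least 12 arrays, its share of rises was larger by more than the SD, as given below. The response was called smaller than in Col for 171, 26 and 247 of the raised and 62, 5 and 94 of the lowered probe sets. These probe sets were chosen on the Col response, and so also on the noise of the Col arrays. Over 117 raised probe sets chosen on the mean of the 4 genotypes the shares were 54.6%, 101% and 22.6%, and over 23 lowered ones 69.7%, 91.1% and 27.5%. That mean includes the mutants' own responses, so this choice favours probe sets that keep the response. The median rise in Col over the 117 was 1.97. These shares are therefore those of another set of probe sets, not a correction of the first.

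**Figure D3:**
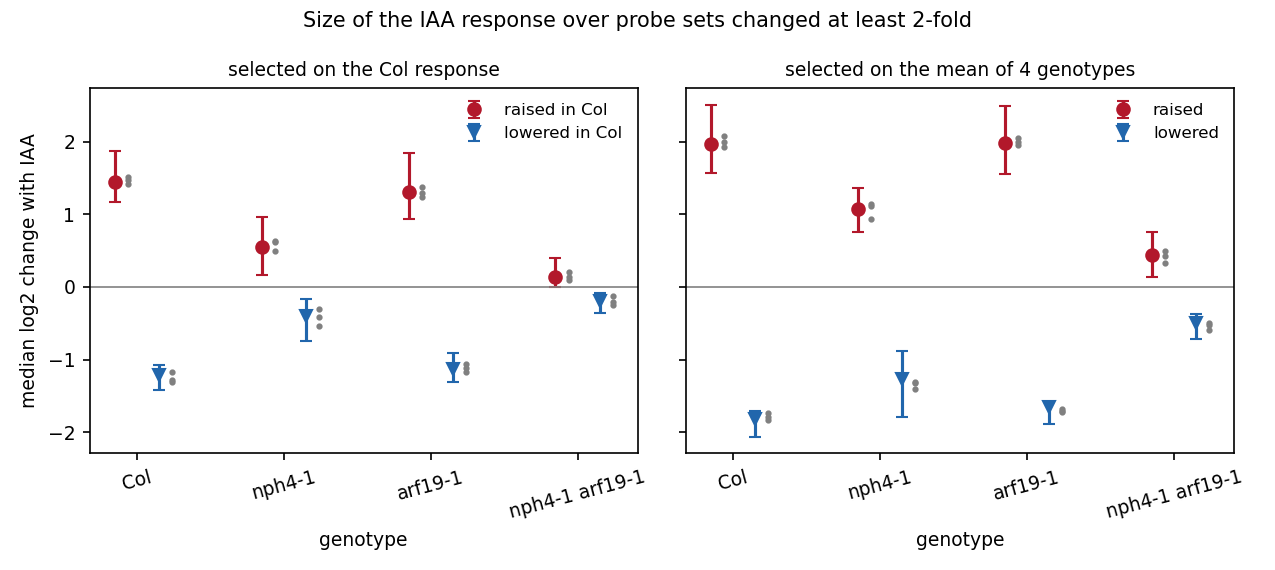
Median log2 change with IAA by genotype over probe sets raised (circles) or lowered (triangles) at least 2-fold, with bars from the lower to the upper quartile of probe sets and grey points for single arrays. Chosen on Col (left), the median rise was 1.44 in Col and 0.14 in nph4-1 arf19-1, and chosen on the mean of 4 genotypes (right) the double mutant kept 22.6% of the rise.

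Whether both mutations add up was tested as the double mutant's response minus what the single mutants' responses sum to. For 13 of the 15 probe sets higher than the sum, among them AT4G25250, EXPB1, AT2G23060 and AT4G37900, the sum would end below the floor, which leaves only a positive value, and no size is given for them. GH3.3 responded less than that sum (log2 -2.11, SE 0.35, adjusted p = 0.01), with responses of 5.63 in Col, 3.97 in nph4-1, 5.78 in arf19-1 and 2.00 in the double mutant, but the sum would end at 14.09, above the highest signal of the arrays. AT4G38410 (1.59, 1.75, 2.05 and 0.39) was lower than the sum (-1.82, SE 0.32), and so was AT1G23340 (-1.28, SE 0.23). The peroxidase AT2G18980 was higher by 1.20 (SE 0.20), having fallen in nph4-1. In all, 28 probe sets passed, 15 higher and 13 lower. The UGT list was higher with none called (UGT85A4 0.98, SE 0.35, adjusted p = 0.011, adjusted p = 0.94 with an estimated correlation). With array quality weights 43 passed, and 17 among probe sets above the floor on at least 12 arrays, while many of the responses start or end at the floor.

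The last comparisons asked how the mutants differed from Col without IAA. In the double mutant GH3.3 was 6.02-fold higher (log2 2.59, SE 0.18), the jasmonate- and ethylene-responsive defensins PDF1.2 (at least 5.31-fold, SE 0.47) and PDF1.2b (4.44-fold, SE 0.35) were higher, APL3, a subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase, was 3.67-fold higher (SE 0.21) and AT1G19960 3.58-fold (SE 0.21). AT1G19530 was lower (log2 -2.74, SE 0.34), and EXPA8 (-2.48, SE 0.27), AT5G01870 (-2.12, SE 0.16), AT3G15450 (-1.61, SE 0.26) and AT5G62280 (-1.60, SE 0.25) were also lower. These 10 calls held in every alternative that tested the gene. In total 2096 probe sets differed, 1108 higher and 988 lower, and 236 at least 2-fold. The split depended on scaling, with 52.9% higher as deposited, 47.1% after quantile normalization and 51.8% with each array at the same median. The count was 1345 without Col control 3, 3581 without Col control 2, 1169 without double-mutant control 2, 1214 without double-mutant control 3 and 759 in a fit of the arrays compared.

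By list, the double mutant without IAA had 4 of 9 XTH genes lower, XTH26 (log2 -1.28, SE 0.25), XTH33 (-0.86, SE 0.10), XTH20 (-0.70, SE 0.14) and XTH18 (-0.52, SE 0.14), and the list was lower (adjusted p = 0.0021, adjusted p = 0.21 with an estimated correlation). Of 13 expansins 4 were higher, among them EXLB1 (0.81, SE 0.18) and EXPA4 (0.76, SE 0.20), and 4 lower, among them EXPA8 and the root hair expansin EXPA7 (-0.64, SE 0.19). HAT2 was higher (0.75, SE 0.11), as was PDC2 of the hypoxia list (1.37, SE 0.30). Of 40 class III peroxidases 9 were higher, with AT2G41480 at 1.61 (SE 0.24) and AT4G36430 at 1.50 (SE 0.22), and 11 lower, with AT1G44970 at -1.23 (SE 0.14) and AT3G49960 at -1.09 (SE 0.10). UGT glycosyltransferases were higher (7 of 31, UGT84A3 1.09, SE 0.20, with UGT76C2 lower at -0.66, SE 0.11, adjusted p = 0.0045), and so were CYP71B enzymes (5 of 9, CYP71B37 0.75, SE 0.15, adjusted p = 0.0021). Tetraspanins were lower (2 of 7, TET10 -0.40, SE 0.12, adjusted p = 0.0089), as were cytosolic ribosomal proteins (list median log2 -0.055, 5 of 103, AT3G14600 -0.31, SE 0.07, adjusted p = 0.02). With an estimated correlation these adjusted p-values were 0.44, 0.22, 0.44 and 0.94. The omission of 1 control array of Col or of the double mutant ended the calls of EXPA7, EXPA4, XTH18 and TET10, with adjusted p up to 0.16, and a fit of the arrays compared those of XTH20, CYP71B37 and AT3G14600.

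In nph4-1 without IAA EXPA8 (log2 -2.04, SE 0.27), AT5G57760 (-1.45, SE 0.26), PR-1-LIKE (-1.42, SE 0.16), AT2G20670 (-1.21, SE 0.26) and AT5G62280 (-1.20, SE 0.25) were lower, and PDF1.2 (at least 3.68-fold, SE 0.47), PDF1.2b (2.78-fold, SE 0.35), AT2G22510 (2.47-fold, SE 0.20), AT5G38020 (2.30-fold, SE 0.23) and AT2G43530 (2.17-fold, SE 0.27) were higher. GH3.3 was higher by 1.02 (SE 0.18). In total 359 probe sets differed, 190 higher and 169 lower. The split depended on scaling, with 52.9% higher as deposited, 41.1% after quantile normalization and 40% with each array at the same median. The count was 211, 1353 and 166 without Col control 1, 2 or 3, 176, 190 and 111 without nph4-1 control 1, 2 or 3, 620 without nph4-1 IAA 1 and 23 in a fit of the arrays compared. The calls of EXPA8, PR-1-LIKE and AT2G22510 held in every alternative that tested the gene, and each of the other genes named in this comparison lost its call in at least 1.

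In arf19-1 without IAA 129 probe sets differed, 53 higher and 76 lower, and 11 by at least 2-fold. AT5G48490 (log2 -1.31, SE 0.24), AT5G01015 (-0.90, SE 0.14), ARL, a regulator of cell expansion (-0.89, SE 0.21), AT1G62510 (-0.84, SE 0.13) and AT1G22690 (-0.84, SE 0.12) were lower, and AT2G22510 (0.97, SE 0.20), AT3G45710 (0.92, SE 0.21), AT1G64590 (0.87, SE 0.17), AT2G16760 (0.82, SE 0.17) and the monolignol glucosyltransferase UGT72E2 (0.80, SE 0.18) were higher. All 10 lost their calls in a fit of the arrays compared, in which 1 probe set passed. The share higher was 41.1%, against 28.5% after quantile normalization and 30.5% with each array at the same median. The count was 35, 924 and 59 without Col control 1, 2 or 3, 71 and 28 without arf19-1 control 2 or 3, 235 without nph4-1 IAA 1, 211 with array quality weights and 201 with the replicate number as a block.

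By list without IAA, UGT glycosyltransferases were higher in nph4-1 (3 of 31, UGT72E2 0.77, SE 0.18, adjusted p = 0.0052, adjusted p = 0.81 with an estimated correlation) and in arf19-1 (1 of 31, UGT72E2, adjusted p = 0.0023, adjusted p = 0.69 with an estimated correlation). XTH genes were lower in arf19-1 (1 of 9, XTH33 -0.63, SE 0.10, adjusted p = 0.046, adjusted p = 0.69 with an estimated correlation). Photosynthesis genes encoded in the plastid genome were higher in nph4-1 (2 of 42, psbH 0.99, SE 0.23, and petB 0.41, SE 0.10, adjusted p = 6.5e-07), in arf19-1 (none of 42, rbcL 0.91, SE 0.44, adjusted p = 0.00017) and in the double mutant (2 of 42, psbH 0.72, SE 0.23, adjusted p = 0.0045), and with an estimated correlation these adjusted p-values were 0.81, 0.94 and 0.94. Plastid-encoded ribosomal protein and polymerase genes were also higher in nph4-1 (1 of 19, rps2 0.98, SE 0.25, adjusted p = 4.9e-05), in arf19-1 (none of 19, rps4 0.79, SE 0.32, adjusted p = 8e-04) and in the double mutant (none of 19, rpl14 0.91, SE 0.48, rps14 -0.94, SE 0.55, adjusted p = 0.041), and with an estimated correlation these were 0.81, 0.94 and 0.94. Over both lists the plastid median differed from Col by 0.54 in nph4-1, 0.43 in arf19-1 and 0.35 in the double mutant, and without control array 3 of each single mutant by 0.31 in nph4-1 and 0.19 in arf19-1. The median of mitochondrial transcripts deviated together with that of plastid transcripts from array to array within groups (Pearson r = 0.82 over 24 arrays, permutation p = 1e-05, the smallest the permutations can give, Spearman rho = 0.67, permutation p = 0.00069). The permutations shuffled all 24 deviations freely. Deviations from the mean of a group are not independent, so these p-values may be too small. Without arf19-1 control 3 and nph4-1 control 3, the farthest from the median, r was 0.63. The calls of psbH, petB, rps2, UGT72E2 and XTH33 in nph4-1 or arf19-1 ended in at least 1 alternative. That of psbH in the double mutant (adjusted p = 0.045) ended in 15 of the 24 omissions of 1 array, with adjusted p up to 0.25, and 0 of 42 passed there when adjusted over the list alone.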

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

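Chosen after the results had been seen were the tests of the plastid difference from Col with and without IAA and of the level of the Col controls, of Col control 3, of scaling and of the control arrays alone as sources of the difference without IAA, of shortened RNA, the splits with other effects removed, and the contrast of nph4-1 with arf19-1. The IAA response differed from that of Col, by the test of the difference itself, for 446 probe sets in nph4-1, 41 in arf19-1 and 640 in the double mutant, and the responses of nph4-1 and arf19-1 differed for 305. The response was larger in size than in Col, with a called difference, for 14 probe sets in nph4-1, of which the call of AT2G18980 held in every alternative. It had a log2 response of 0.31 in Col and -1.61 in nph4-1. The response was larger for 4 probe sets in arf19-1 and for 6 in the double mutant. For 2 of the 14, XTH21 among them, and for 1 of the 4, AT3G59370, the floor bars a fall of that size in Col, so that the larger response is not a result.

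The plastid median of the mutants lay above that of Col by 0.46 in log2 with IAA (exact permutation p = 0.0045, 9 arrays against 3, adjusted over both tests p = 0.0091) and by 0.44 without IAA, which did not pass (exact permutation p = 0.064). From array to array within groups the plastid and mitochondrial medians ran together (r = 0.82), so unequal capture of organelle transcripts may account for that spread. The mitochondrial median differed between mutants and Col by 0.03 without and by -0.02 with IAA. This argues against unequal capture shared by both organelles as the whole difference from Col. Unequal capture of plastid transcripts alone would not show in it and was not tested. With the part that follows the mitochondrial median taken out, the plastid difference without IAA was 0.41 (exact permutation p = 0.014, and 0.36 with p = 0.042 without nph4-1 control 3 and arf19-1 control 3). Since the mitochondrial median hardly differed from Col, this step could change little, and it adds no separate support. The permutations took the 9 mutant arrays, which are of 3 genotypes, as a single group. All 3 mutants had their 3 IAA arrays above the 3 Col IAA arrays, but 0 mutants had their 3 control arrays above the 3 Col controls, so a chance level of the Col controls stays open for the difference without IAA. A difference in plastid transcripts between the genotypes stays open as a hypothesis, untested beyond these values.

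The difference between nph4-1 arf19-1 and Col without IAA covered 2096 probe sets. Without Col control 3, the array of that group with the lowest weight, 1345 still passed, which argues against that array as the whole source. Without Col control 2, the other array with a replaced table, 3581 passed, so the count depends strongly on these arrays. Between the IAA arrays, which share no array with this contrast, 91.6% of the 2096 had the same sign, against 67.9% of uncalled ones, and from 81.7% to 91.3% in single pairs of arrays, which argues against array differences limited to the control arrays. With quantile normalization 2137 passed, which argues against scaling between arrays as the source of the count, though not of the split, 52.9% higher before and 47.1% after it. An effect of the genotype is consistent with these values, and growth differences between the cultures stay open, since the design holds nothing that separates them.

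Col control 3 and nph4-1 IAA 1 deviated from their groups together, with a correlation of their deviations of 0.53 across probe sets, which are not independent replicates, while nph4-1 control 3 with arf19-1 control 3 (0.58) and arf19-1 control 1 with double-mutant IAA 1 (0.57) correlated more. In 3′ over 5′ signal both lay above the middle of the range of the other 22 arrays in 5 of 5 control pairs and above all of them in 0. The pairs are not independent, since actin and ubiquitin each occur more than once among them. The arrays arf19-1 control 1 and double-mutant IAA 1 scored higher (1.49 and 1.73 against 0.91 and 0.80) with array weights of 0.55 and 0.51. Over the 18 arrays of the other groups the deviation in 3′ over 5′ signal ran with likeness to the 2 arrays (r = 0.86, exact permutation p = 0.0067), so shortened RNA may account for part of the pattern. The correlation was 0.53 after quantile normalization, which argues against scaling. Handling of these arrays together stays open, since the labels give no batch, and no biological explanation was tested. The labels state that the tables of Col control 2 and 3 were replaced after an earlier release. Whether this bears on the pattern was not tested.

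The arrays of 2 groups of 3 can be split in 10 ways, too few for a share under 0.05. In each of the 7 comparisons of 2 groups 1 split, the real one, gave as many probe sets. For the IAA response the real split gave 2026 in Col, 397 in nph4-1, 1592 in arf19-1 and 66 in the double mutant, and the highest other split 491, 1, 1 and 10. The labels state no pairing by array number. The deviations of control and IAA arrays of the same number correlated in nph4-1 (0.42, 0.32 and 0.32) and in the double mutant (0.5, 0.18 and 0.43). Arrays of different numbers also did, such as Col control 3 with nph4-1 IAA 1 (0.53), so pairing was not established. In the double mutant the highest other split that parted all arrays of the same number gave 1. Without IAA the real split gave 359 for nph4-1, 129 for arf19-1 and 2096 for the double mutant, and the highest other split 4, 14 and 18.

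For the differences in response, 15 of 100 splits gave as many probe sets as the real 446 in nph4-1 (highest 1937), 10 of 100 as the real 41 in arf19-1 (highest 1824), 14 of 100 as the real 640 in the double mutant (highest 4098) and 14 of 100 as the real 305 between the single mutants (highest 741), so chance was not excluded by these. The splits with several times the real count point to a structure of the samples, since exchanging genotypes within 1 treatment turns the difference without IAA into one of response. With those other effects removed, which was chosen after these results, 1, 2, 1 and 1 of 100 splits gave as many, the real one included. The highest others gave 142, 41, 62 and 11, so for arf19-1 another split equalled the real count. For nph4-1, the double mutant and the contrast of the single mutants this argues against a chance split of the arrays. The splits did not keep array numbers together. Chance between cultures is not excluded, since the labels do not say whether the arrays of a group are separate cultures. For the 28 probe sets of the non-additivity, 13 of them with a sign that the floor fixes, 1 of 100 splits gave as many, the real one. The highest other gave 8, and 4 with other effects removed, which argues against a chance split of the arrays, with the same limit on cultures.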

How the results depend on the processing

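The adjustment over all probe sets, the fit without both outlying arrays and the minimum of 12 arrays above the floor were chosen after seeing the data. No called gene list changed its sign with quantile normalization or equal medians, while lists without a call did. The split of the calls did turn, from 52.9% higher to 41.1% after quantile normalization in nph4-1 without IAA and from 52.9% to 47.1% in the double mutant. Quantile normalization, equal medians, plain eBayes, the adjustment over all probe sets and the fit without both outlying arrays left every count within 1.5 times and every share within 1 SD. The pseudocounts were not run. At an adjusted p under 0.01 the counts were 1280, 260, 1056 and 28 for the IAA response in Col, nph4-1, arf19-1 and the double mutant, 115, 29 and 977 for the 3 mutants without IAA, 243, 27 and 411 for the differences in response, and 8 for the non-additivity. With a minimum of 2-fold they were, in the same order, 405, 101, 342, 18, 41, 11, 236, 183, 19 and 307. Both come from a stricter threshold. Fitting only the arrays compared gave 893 for Col, 153 for nph4-1, 23, 1 and 759 without IAA, and 214 and 19 for the differences of nph4-1 and arf19-1. It has fewer arrays for the spread, and it does not pool the spread of the other groups. The spread was unequal. The deviations of an array from its group had an SD of 0.162 to 0.236 across probe sets in the Col controls. In arf19-1 with IAA this SD was 0.082 to 0.105. How much of the drop comes from each was not tested. The fit of only the arrays compared gave no value for the non-additivity, which uses all arrays. Array quality weights gave 838, 5231 and 218 for nph4-1, arf19-1 and the double mutant with IAA, 211 for arf19-1 without IAA, 43 for the non-additivity and a share of 87% for falls in arf19-1. The replicate block gave 201 for arf19-1 without IAA. The filter on dim probe sets gave 27 for the difference of arf19-1, and a minimum of 12 arrays above the floor gave 17 for it, 17 for the non-additivity and 15.7% for rises in the double mutant. Chosen on the mean of the 4 genotypes, the shares were 54.6%, 101% and 22.6% of rises in nph4-1, arf19-1 and the double mutant, and 69.7% and 27.5% of falls in nph4-1 and the double mutant. With an estimated correlation camera called 0 lists in every contrast but the difference of the double mutant, where it called 1. Fry, which asks another question, called 11 lists in Col, 5 in arf19-1, 2 in the difference of the double mutant, and 0 in the double mutant with IAA, in nph4-1 and arf19-1 without IAA, in the difference of arf19-1 and in the non-additivity. Except for the thresholds, the cause was not tested.

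Leaving out 1 array at a time, the IAA response ran from 258 to 445 in nph4-1 and from 33 to 85 in the double mutant. Without IAA the counts ran from 111 to 1353 in nph4-1, from 28 to 924 in arf19-1 and from 1169 to 3581 in the double mutant, with the highest each time without Col control 2. Shares in arf19-1 ran from 85.3% to 94% of rises and from 85.3% to 94.6% of falls. The other counts and shares stayed within 1.5 times or 1 SD. A group left with 2 arrays takes its spread from the pooled fit. Signals under the floor limit every fold that starts or ends there.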

Other observations

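The tests reported here were chosen after the values had been seen. The single mutants were compared directly by the contrast of their IAA responses, which was not in the design. Of the 305 probe sets that differed, 189 were raised by IAA in Col, and the rise was smaller in nph4-1 for 184 of them and smaller in arf19-1 for 5. Of the 92 lowered in Col, the fall was smaller in nph4-1 for 89 and smaller in arf19-1 for 3. The named genes with the smaller response in arf19-1 were PUCHI, a transcription factor of lateral root primordia (log2 response 1.45 in Col, 0.76 in nph4-1, 0.30 in arf19-1, difference 0.46, SE 0.11, adjusted p = 0.024), the ubiquitin ligase PUB23 (1.20, 0.97, 0.13, difference 0.84, SE 0.20, adjusted p = 0.026) and the peroxidase AT2G39040 (-1, -0.84, 0.11, difference -0.95, SE 0.20, adjusted p = 0.012).

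Without IAA GH3.3 was 6.02-fold higher in the double mutant than in Col, and a candidate explanation is a higher auxin response there without added IAA. Over the 249 probe sets raised at least 2-fold by IAA in arf19-1, which shares no array with this comparison, the median log2 difference of the double mutant from Col without IAA was -0.174, and 66.3% of them were lower. Of these, 65 were called lower and 15 higher. In nph4-1 the median was -0.151 and 67.1% were lower. These probe sets kept 13.1% of their arf19-1 response in the double mutant, so they could not report a higher auxin response there. The values therefore decide nothing about this explanation, which stays open.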
